A study of Homo sapiens with 36 samples.

How the data were processed

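The data are the authors' processed values of 36 microarrays from the human lines DU145 and CCRF-CEM, each as SLFN11-proficient parent and SLFN11-knockout cells, with treatment none or camptothecin for 6 h or 12 h. Per the labels cells grew in RPMI1640 with 10% FBS, camptothecin was used at 250 nM, and DMSO was the other addition named. The labels do not give the harvest time of the control cells. Total RNA was extracted with TRIzol, purified on columns with DNase treatment, and 100 ng was reverse transcribed, amplified and biotin labelled with the GeneChip WT Plus kit. Per the submitters' processing notes the values come from RMA in Partek, whose versions are not given. The deposited values are log2 probe-set signals by the authors' normalization, ranged from 0.97 to 13.92 and were used as deposited. The genome build is not given in the sources used here.

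The deposited values covered 352859 probe sets. Of these 259224 carried exactly 1 gene symbol, 13116 several and 80519 none. Of 22320 symbols 20529 were current, 1726 were updated through their synonyms and 65 were kept without a match. A gene was represented by its probe set with the highest mean over the 36 arrays, among those with exactly 1 symbol, which gave 22260 genes, 17902 of them protein coding. Genes had a median of 10 probe sets, and 2598 had 1. Probe sets with several symbols or none were left out except in the alternative that tested all of them. No array and no column was left out. No gene was left out for a low signal. The lower quartile of the arrays was 2.96 to 3.04, and the size of a change is uncertain for a gene with a group mean near or below it. Examples with a mean below 3.04 in a group compared are DCN, SLC9B1, ARL14 and ZCWPW2 in DU145 and GBP7, TPPP2, H2AC7, SLC22A10 and CDC42BPA in CCRF-CEM.

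Each line was fitted separately with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with its 18 arrays in 6 groups and 12 residual degrees of freedom, without a replicate block. Contrasts were camptothecin minus control at 6 h and 12 h in parent and in knockout cells, the genotype difference (the log2 change in parent cells minus that in knockout cells) at each time, and knockout minus parent among controls, 14 in all. The Benjamini-Hochberg method adjusted p over the genes of a contrast, and a gene passed at an adjusted p below 0.05. The comparisons at 6 h and 12 h use the same control arrays, as do the genotype difference and the untreated comparison, so no overlap between these was computed. SE is the moderated standard error of limma. Whether the genotype difference differed between the lines was tested in a fit of all 36 arrays with 12 groups. Files were read with the data.table package (version 1.17.8) and Python 3.11.15.

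Gene lists numbered 25, and the results of 1 list and 1 named gene are not printed. The others were the immediate early, AP-1 family, NF-kB and cytokine, integrated stress and unfolded protein response, interferon-stimulated, replication-dependent histone, DNA replication, mitotic, G1/S cyclin and E2F, DNA damage checkpoint and homologous recombination, heat shock, BCL2 family, topoisomerase and tyrosyl-DNA phosphodiesterase, Schlafen family, chromatin remodeler, ribosomal protein, ribosome biogenesis, sterol synthesis, housekeeping and mitochondrially encoded genes, and epithelial, T-lineage, B-lineage and myeloid, and fibroblast and endothelial markers. Of the 13 mitochondrially encoded genes 0 were measured, so 24 lists were tested, and 20 of the 49 histone genes were. Members passing were counted over all genes and again after adjustment over the list alone. Lists were tested with camera with an estimated correlation, adjusted over the lists of a contrast, and with a preset correlation of 0.01 as an alternative, under which 34 of 336 list results became calls and no call was lost. Calls of the lines were compared by Fisher's exact test per direction, the p adjusted over these tests.

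Genes were named by a rule: SLFN11, the 10 with the largest positive and the 10 with the largest negative genotype difference per contrast, 6 in each direction per camptothecin contrast and 10 per untreated comparison where all treated or knockout arrays lay on 1 side of the others, protein coding only, and in each case the largest are printed. Members of the lists serve as examples. The design, the lists, the naming rule and the alternatives were chosen before the data were examined, except that leaving out each replicate was added for the overlap and the comparison of the lines after seeing the data. The alternatives were a replicate block, 1 fit of all arrays, only the arrays of the groups compared, a variance trend with robust moderation, array weights, a filter on level, a shift of each array to equal housekeeping medians, cyclic loess, the mean of all probe sets of a gene, all probe sets, leaving out each replicate, an adjusted p below 0.01, the preset correlation and, for the overlap, a change of at least 2-fold.

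The method was tested on simulated data with the spread of these arrays and 50 changed genes of each size among 22260. At 6 h in parent cells it recovered 42% of log2 changes of 1 and 94% of changes of 2 in DU145, and 58% and 92% in CCRF-CEM. For the genotype difference it recovered 30% and 78%, and 32% and 78%. In a contrast without simulated changes it called 0 genes in either line. False calls were 6 of 130 in DU145 and 5 of 138 in CCRF-CEM at 6 h in parent cells, and 11 of 113 and 8 of 112 for the genotype difference, so there the false share lay above the level of 0.05 aimed at. In this simulation differences below 2-fold between genotypes were thus missed more often than found. The changes were placed in parent cells at 6 h only, and both lines used the same random draws. The share found depends on how many genes change, so these rates may not hold in the real comparisons. With 3 arrays per group, a gene that did not pass may not be counted as unchanged.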

Results

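SLFN11 is a nuclear protein of the Schlafen family that acts at stalled replication forks and whose presence makes cancer cells sensitive to drugs that damage replicating DNA. The series examined how its loss alters the transcriptional response to camptothecin, a compound that traps topoisomerase I on DNA and so blocks replication forks and elongating RNA polymerase. Expression was measured in DU145, a human prostate carcinoma line, and in CCRF-CEM, a human T-cell acute lymphoblastic leukaemia line. Each line was present as SLFN11-proficient parent cells and as SLFN11 knockout cells, without camptothecin and after 6 h and 12 h in 250 nM camptothecin. The 12 groups held 3 arrays each, 36 in all. Each line had a single knockout group, and the labels do not say whether it is a clone or a pool. The loss of SLFN11 and the origin of these cells are therefore not separated in any comparison of the genotypes. Array medians lay between 4.78 and 4.86 on the log2 scale. Arrays of 1 group correlated with each other at Pearson r of 0.979 to 0.988 across genes, each represented by its brightest probe set. No pair of arrays held identical values. Markers of the labelled lines were where they should be for an epithelial and a T-cell line. In untreated parent cells KRT18, an epithelial keratin, stood at 11.60 ± 0.12 in DU145 and 7.68 ± 0.41 in CCRF-CEM (log2 mean ± SD, n = 3). CD3E, a subunit of the T-cell receptor complex, stood at 6.37 ± 0.21 and 11.86 ± 0.07.

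The targeted gene was examined first. SLFN11 had 11 probe sets, and they did not move together. The brightest, which stood for the gene in all further tests, did not pass between untreated knockout and parent cells in either line. Its log2 differences were 0.41 ± 0.17 in DU145 (adjusted p = 0.15) and 0.34 ± 0.12 in CCRF-CEM (adjusted p = 0.231). In control, 6 h and 12 h cells its mean level was 8.56, 9.11 and 9.27 in DU145 parent and 8.97, 9.04 and 9.55 in DU145 knockout cells, and 9.48, 9.32 and 9 in CCRF-CEM parent and 9.82, 10.08 and 9.99 in CCRF-CEM knockout cells. At 12 h of camptothecin it rose in DU145 parent and knockout cells, by 0.71 ± 0.17 and 0.58 ± 0.17 (adjusted p = 0.0208 and 0.0469), and fell in CCRF-CEM parent cells, by 0.48 ± 0.12 (adjusted p = 0.00961). The CCRF-CEM genotype difference at 12 h was -0.65 ± 0.17 (adjusted p = 0.0271). Probe set 16843409 was lower in the knockout cells of both lines, by -2.85 ± 0.48 in DU145 (adjusted p = 0.00649) and -1.07 ± 0.14 in CCRF-CEM (adjusted p = 0.00233). In DU145 probe sets 16843407 and 16843408 were also lower, at -0.85 ± 0.20 and -1.52 ± 0.36, while 16843410 and 16843412 were higher, at 0.70 ± 0.15 and 2.14 ± 0.52. The last is uncertain in size, since its mean in parent cells was 3.00, near the lower quartile of the arrays. Adjustment here ran over all 352859 probe sets, and these were singled out after their values were seen. The position of the edit in the gene is not given in the sources used here, so a probe set outside it checks nothing and the labels are tested in part.

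In DU145 parent cells camptothecin raised stress-response transcription factors most. ATF3, an immediate early gene of the ATF family, rose by 4.90 ± 0.31 log2 at 6 h and 4.05 ± 0.31 at 12 h (± SE, n = 3 arrays per group). DDIT3, which encodes the stress factor CHOP, rose by 4.04 ± 0.31 and 3.16 ± 0.31, and CHAC1, a glutathione-degrading enzyme, by 3.05 ± 0.17 and 2.54 ± 0.17. At 6 h the histone gene H2BC15 (2.90 ± 0.24), the thioredoxin inhibitor TXNIP (2.81 ± 0.20) and the DNA-damage-inducible GADD45A (2.64 ± 0.10) followed. At 12 h the next were the chemokine CCL20 (2.56 ± 0.24), GADD45A (2.21 ± 0.10) and SESN2 (2.19 ± 0.14), which restrains mTORC1. The amino acid transporter SLC7A3 (-2.80 ± 0.83), KIF25 (-2.23 ± 0.33), the receptor ROR1 (-2.13 ± 0.22) and the chromatin remodeler subunit ARID1B (-2.12 ± 0.25) fell most at 6 h. At 12 h those were decorin, DCN (-2.56 ± 0.60), LPP (-2.50 ± 0.16), RIMS2 (-2.42 ± 0.32) and MSRA (-2.16 ± 0.53).

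Of the 40 immediate early genes, transcription factors and regulators induced without new protein synthesis, 24 rose and 0 fell in DU145 parent cells at 6 h, and 16 did not pass. Adjusted over the list alone 27 rose and 2 fell. At 12 h 19 rose and 21 did not pass (27 rose and 1 fell adjusted over the list alone). PPP1R15A, a regulatory subunit of the phosphatase that acts on eIF2 alpha, rose by 2.34 ± 0.17 at 6 h. JUN rose by 1.89 ± 0.12, IER2 by 1.72 ± 0.17, MYC by 1.61 ± 0.14 and EGR1 by 1.28 ± 0.14. The list moved up against the other genes at both times, with adjusted p = 0.000229 and 0.00096 with an estimated correlation. The AP-1 family rose in 9 of 13 members at 6 h and 6 at 12 h (11 and 10 adjusted over the list alone). JUNB rose by 1.79 ± 0.13 and JUND by 1.26 ± 0.12 at 6 h, and the family gave the same adjusted p as the immediate early genes.

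Inflammatory and proteotoxic stress genes rose in the same cells. Of 20 NF-kB and cytokine genes 12 rose at 6 h and 9 at 12 h with 0 falling (13 at each time adjusted over the list alone), with adjusted p = 0.00117 and 0.00247 with an estimated correlation. TNFAIP3, a feedback inhibitor of NF-kB, rose by 1.97 ± 0.09 and 1.60 ± 0.09. CXCL8, a neutrophil chemokine, rose by 1.64 ± 0.13 and 1.80 ± 0.13. Of 20 genes of the integrated stress and unfolded protein responses 13 and 12 rose with 0 falling (adjusted p = 0.000109 and 0.000162 with an estimated correlation). Adjusted over the list alone 14 rose and 1 fell, and 15 rose. At 6 h they included asparagine synthetase, ASNS (1.73 ± 0.13), DDIT4, an mTORC1 inhibitor (1.93 ± 0.21), and HERPUD1 of endoplasmic reticulum degradation (1.43 ± 0.11).

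Cell cycle genes of DU145 parent cells moved in opposite directions. Of 26 mitotic genes 15 fell at 6 h and 13 at 12 h with 0 rising (18 and 16 adjusted over the list alone), with adjusted p = 0.000823 and 0.00096 with an estimated correlation. The kinase PLK1 stood at -1.05 ± 0.12 and -1.26 ± 0.12 and cyclin B1, CCNB1, at -0.57 ± 0.11 and -0.86 ± 0.11. Of 11 G1/S cyclin and E2F genes 6 and 7 rose with 0 falling (adjusted p = 0.00427 and 0.00096). Adjusted over the list alone 7 rose, and 7 rose and 1 fell, and cyclin E1, CCNE1, rose by 1.00 ± 0.20 and 1.54 ± 0.20. Of 40 DNA replication genes 16 rose and 2 fell at 6 h and 22 rose and 1 fell at 12 h (adjusted p = 0.0493 and 0.00578 with an estimated correlation). Adjusted over the list alone 23 and 31 rose and 2 fell at each time, and CDC6, a licensing factor, rose by 0.86 ± 0.10 and 1.03 ± 0.10. The 20 measured replication-dependent histone genes split 3 up and 2 down at 6 h (the same counts adjusted over the list alone, adjusted p = 0.535 with an estimated correlation). At 12 h they split 1 up and 8 down (1 and 11 adjusted over the list alone, adjusted p = 0.0127), with H2BC14 at -1.84 ± 0.12. Of 12 sterol synthesis genes 4 rose at 6 h (5 adjusted over the list alone, adjusted p = 0.0233), HMGCS1, which makes HMG-CoA, by 1.01 ± 0.12, and 1 at 12 h (adjusted p = 0.665). Of 20 chromatin remodeler genes 1 rose and 6 fell at 6 h and 0 rose and 6 fell at 12 h (1 and 7 at each time adjusted over the list alone). This was no list call (adjusted p = 0.122 and 0.0546).

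Over all 22260 genes, limma called 2247 changed at 6 h in DU145 parent cells (1263 higher, 984 lower, 396 by at least 2-fold) and 1711 at 12 h (846 higher, 865 lower, 293 by at least 2-fold). The count was 1398 at 6 h without replicate 3 of the treated arrays and 1133 at 12 h without replicate 2 of the treated arrays. At 6 h 56.2% of the changed genes were higher, and 28.8% were with each array shifted to equal housekeeping medians.

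In DU145 knockout cells the zinc finger gene ZNF726 rose by 2.40 ± 0.21 log2 at 6 h, the T-box factor EOMES by 2.12 ± 0.39 and 2.18 ± 0.39, and the sodium/hydrogen exchanger SLC9B1 by 2.06 ± 0.43 and 2.10 ± 0.43 (± SE, n = 3). In parent cells ZNF726 and EOMES rose as well, by 1.90 ± 0.21 and 2.22 ± 0.39 at 6 h. At 12 h CNIH2 rose by 2.21 ± 0.23, MYB by 2.04 ± 0.23 and CCNE1 by 1.93 ± 0.20. The histone genes H2BC14 (-2.54 ± 0.12) and H1-5 (-2.10 ± 0.17), RIMS2 (-2.35 ± 0.32) and the hyaluronidase CEMIP (-2.14 ± 0.26) fell most at 6 h. At 12 h those were ZNF407 (-2.31 ± 0.34), RIMS2 (-2.31 ± 0.32), LPP (-2.29 ± 0.16) and the exocyst gene EXOC6B (-2.21 ± 0.20), of which RIMS2, LPP and EXOC6B were also among the most fallen genes of parent cells. ATF3 did not pass, at -0.79 ± 0.31 and -0.27 ± 0.31, nor did DDIT3, at -0.23 ± 0.31 and -0.14 ± 0.31. DDIT4 fell by 1.05 ± 0.21 and 0.94 ± 0.21.

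Immediate early genes in DU145 knockout cells rose in 2 and fell in 3 of 40 cases at 6 h (adjusted p = 0.697 with an estimated correlation, median 0.06 and mean -0.01) and rose in 5 and fell in 2 at 12 h (0.465). The counts adjusted over the list alone were 2 and 3, and 7 and 2. NF-kB and cytokine genes fell in 4 of 20 cases at 6 h and rose in 1 and fell in 1 at 12 h (adjusted p = 0.331 and 0.866). Stress and unfolded protein response genes fell in 1 of 20 cases at 6 h and rose in 2 and fell in 2 at 12 h (0.968 and 0.946). Their median of 0.06 at 6 h and mean of 0.03 at 12 h lay above 0, while the list test pointed down. Of the 20 histone genes 10 fell and 1 rose at 6 h and 11 fell and 0 rose at 12 h (adjusted p = 0.00467 and 0.00384 with an estimated correlation). With p adjusted over the list alone 11 fell and 1 rose, and 12 fell and 1 rose, with the linker histone gene H1-3 at -1.60 ± 0.30 and -1.35 ± 0.30. Mitotic genes fell in 15 and 16 of 26 cases with 0 rising (adjusted p = 0.00217 and 0.000866), and G1/S genes rose in 8 and 7 of 11 with 0 falling (adjusted p = 0.00281 and 0.00195). DNA replication genes rose in 13 and 25 of 40 with 2 falling at each time (adjusted p = 0.178 and 0.0129).

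The limma fit called 1940 genes changed at 6 h in DU145 knockout cells (1185 higher, 755 lower, 243 by at least 2-fold) and 2232 at 12 h (1405 higher, 827 lower, 336 by at least 2-fold). Without replicate 1 of the treated arrays the count at 6 h was 1168, and without replicate 2 of the treated arrays the count at 12 h was 1375. The share of higher genes was 61.1% and 62.9%, against 48.9% and 51.6% after cyclic loess. Parent and knockout cells had 350 risen genes in common at 6 h (67.2 expected for independent lists) and 427 fallen genes (33.4 expected). At 12 h they had 264 (53.4) and 434 (32.1). These cells share no arrays, but the fit gives each gene 1 estimate of spread for both. The lists are therefore not independent, and the expected counts are only a rough guide.

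**Figure D1:**
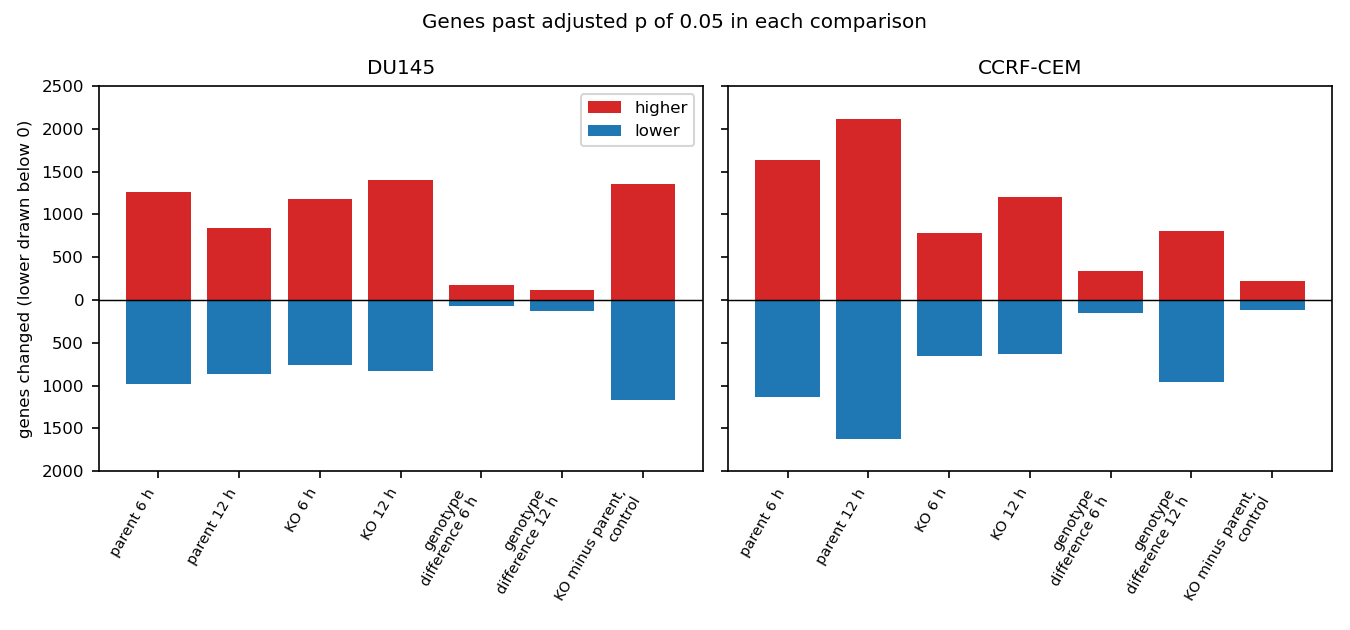
Number of genes called higher (above 0) and lower (below 0) at an adjusted p under 0.05 by limma in each comparison, for DU145 and CCRF-CEM, out of 22260 genes. The genotype differences held 248 and 251 genes in DU145 at 6 h and 12 h, and 497 and 1761 in CCRF-CEM.

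The difference between the genotypes was tested directly in DU145, as the log2 change in parent cells minus that in knockout cells. It was largest for ATF3, at 5.69 ± 0.44 at 6 h (± SE, adjusted p = 9.3e-06) and 4.32 ± 0.44 at 12 h (adjusted p = 0.00056), and for DDIT3, at 4.26 ± 0.44 and 3.30 ± 0.44. DDIT4 (2.98 ± 0.30 and 2.54 ± 0.30), CHAC1 (2.85 ± 0.24 and 2.19 ± 0.24), CCL20 (2.79 ± 0.33 and 2.59 ± 0.33), the small GTPase gene ARL14 (2.63 ± 0.35 and 1.93 ± 0.35) and TXNIP (2.47 ± 0.28 and 2.04 ± 0.28) followed at both times. The signal of ARL14 was low, with group means of 2.27 to 3.88 against array medians of 4.78 or more, so the size of its difference is uncertain. They were joined by PPP1R15A (2.44 ± 0.25), SESN2 (2.36 ± 0.19) and CXCL8 (2.31 ± 0.18) at 6 h, and by the pantetheinase VNN2 (2.56 ± 0.48) and SLC12A3 (2.21 ± 0.39) at 12 h. The difference was most negative for NLRP4 (-1.69 ± 0.37), the TNF receptor TNFRSF1B (-1.61 ± 0.32), ENPP5 (-1.54 ± 0.33) and UBE2V1 (-1.54 ± 0.29) at 6 h. At 12 h this held for the protease gene TMPRSS11A (-2.42 ± 0.38), KHDC1 (-2.27 ± 0.51), EML1 (-2.02 ± 0.39) and UBE2V1 (-1.93 ± 0.29).

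Immediate early genes, the group the series title names, differed between the DU145 genotypes at both times. The genotype difference passed above 0, here and below called larger, for 17 of 40 members at 6 h (22 adjusted over the list alone). It passed below 0, called smaller, for 0. These words give the sign of the difference and not which genotype changed more. The median difference was 0.69 log2, with adjusted p = 0.000127 with an estimated correlation. At 12 h the genotype difference was larger for 11 members (17 larger and 1 smaller adjusted over the list alone, median 0.44, adjusted p = 0.00795). IER2 (2.22 ± 0.24), the Kruppel-like factor KLF6 (2.10 ± 0.14), JUN (1.86 ± 0.17) and EGR1 (1.32 ± 0.20) were among those at 6 h, whereas FOS (0.59 ± 0.24) did not pass. AP-1 genes were larger in 7 and 4 of 13 cases (10 and 5 adjusted over the list alone; adjusted p = 0.000127 and 0.00843 with an estimated correlation). Stress and unfolded protein response genes were larger in 8 and 7 of 20 cases (13 and 10; adjusted p = 4.65e-05 and 0.000301), with ASNS at 1.88 ± 0.18 and 1.46 ± 0.18. NF-kB and cytokine genes were so in 6 and 5 of 20 (10 and 9; adjusted p = 0.000236 and 0.00795), with the caspase inhibitor BIRC3 at 1.91 ± 0.18 and 1.56 ± 0.18. Histone genes were larger in 5 of 20 cases at 6 h (13 adjusted over the list alone, median 0.85, adjusted p = 0.00257) and in 0 at 12 h (2 adjusted over the list alone, adjusted p = 0.788). H2BC14 differed by 1.04 ± 0.16 at 6 h. DNA replication, mitotic and G1/S genes gave no list call at either time. DNA replication genes were larger in 1 and 0 cases (adjusted p = 0.784 and 0.955).

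In DU145 the genotype difference passed for 248 genes at 6 h, 174 higher and 74 lower, 130 of them by at least 2-fold. It passed for 251 at 12 h, 118 higher and 133 lower, 127 by at least 2-fold. At 12 h 47.0% were higher, against 39.5% with arrays shifted to equal housekeeping medians and 54.1% after cyclic loess. Of the 174 higher genes 145 also rose in parent cells, and of the 133 lower genes at 12 h 99 rose in knockout cells. The genotype difference is made of these same changes, so such overlap is partly built in and only describes the genes called. The count at 6 h was 144 and 156 without replicates 1 and 2 of the treated knockout arrays and 146 without replicate 3 of the treated parent arrays. The count at 12 h rested on most of its arrays. It was 62, 48 and 139 without treated knockout replicates 1, 2 and 3, and 159, 99 and 139 without knockout control replicates 1, 2 and 3. It was 86 and 52 without treated parent replicates 2 and 3, and 103, 66 and 109 without parent control replicates 1, 2 and 3.

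CCRF-CEM parent cells raised immediate early and NF-kB genes most. RELB, an NF-kB subunit, rose by 4.08 ± 0.26 log2 at 6 h and 4.64 ± 0.26 at 12 h (± SE, n = 3). The zinc finger factor EGR1 rose by 4.08 ± 0.25 and 5.03 ± 0.25, ATF3 by 3.98 ± 0.13 and 3.63 ± 0.13, and NFKB2, the precursor of NF-kB p52, by 3.79 ± 0.28 and 4.15 ± 0.28. The orphan nuclear receptor NR4A2 rose by 3.55 ± 0.20 and 4.88 ± 0.20, and DUSP4, a phosphatase of MAP kinases, by 3.37 ± 0.43 and 3.68 ± 0.43. DUSP4 started from a parent control mean of 3.34 (SD 0.67), near the lower quartile of the arrays, so the size of its rise is uncertain. GBP7 (-2.43 ± 0.66), RIMS2 (-2.08 ± 0.20), LPP (-2.02 ± 0.18) and C7orf57 (-1.99 ± 0.20) fell most at 6 h. At 12 h IQUB (-2.58 ± 0.43), C7orf57 (-2.42 ± 0.20), TPPP2 (-2.30 ± 0.63) and DNTT (-2.28 ± 0.10), the template-independent polymerase of immature lymphocytes, fell most.

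Of the 40 immediate early genes 21 rose and 3 fell in CCRF-CEM parent cells at 6 h (the same counts adjusted over the list alone) and 23 rose and 1 fell at 12 h (26 and 1). The list gave adjusted p = 0.00438 and 0.00269 with an estimated correlation. JUN rose by 3.29 ± 0.14 and 3.48 ± 0.14 and PPP1R15A by 2.46 ± 0.15 and 2.58 ± 0.15, while MYC fell by 0.79 ± 0.14 and 1.84 ± 0.14. AP-1 genes rose in 6 of 13 cases at 6 h and rose in 6 and fell in 2 at 12 h (adjusted p = 0.00438 and 0.00867). With p adjusted over the list alone they were 6 up and 1 down, and 7 up and 3 down. The probe sets of FOS disagreed. Its brightest did not pass, at 0.30 ± 0.26 and 0.73 ± 0.26, and the mean of its probe sets gave 2.06 and 2.08. NF-kB and cytokine genes rose in 8 and 10 of 20 cases with 0 falling (10 at each time adjusted over the list alone, adjusted p = 0.000184 and 0.000587). At 6 h BIRC3 rose by 3.13 ± 0.22 and CXCL8 by 2.58 ± 0.22. Stress and unfolded protein response genes rose in 10 and fell in 4 of 20 cases at 6 h and rose in 8 and fell in 5 at 12 h (adjusted p = 0.0242 and 0.0416). With p adjusted over the list alone 10 rose and 4 fell, and 11 rose and 6 fell. DDIT3 (2.44 ± 0.21 and 2.98 ± 0.21) and CHAC1 (1.76 ± 0.16 and 1.78 ± 0.16) rose. The endoplasmic reticulum chaperone HSPA5 (-0.79 ± 0.10 and -0.62 ± 0.10) and its partner PDIA4 (-0.59 ± 0.11 and -0.68 ± 0.11) fell.

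Mitotic and T-lineage genes fell in CCRF-CEM parent cells. Of 26 mitotic genes 21 fell at 6 h and 17 at 12 h with 0 rising (22 and 18 adjusted over the list alone, adjusted p = 0.000114 and 0.000587 with an estimated correlation). PLK1 fell by 1.72 ± 0.10 and 1.26 ± 0.10. Of 20 T-lineage markers 11 and 12 fell with 0 rising (13 and 15 adjusted over the list alone, adjusted p = 0.00039 and 0.000551). At 12 h the recombinases RAG1 (-2.05 ± 0.13) and RAG2 (-1.69 ± 0.11) and the lipid-presenting CD1A (-1.93 ± 0.09) were among them. DNA replication genes rose in 12 and 14 of 40 cases and fell in 2 at each time (adjusted p = 0.00675 and 0.0332). Within the list, adjusted over the list alone, 19 rose and 4 fell, and 18 rose and 3 fell. G1/S genes rose in 5 and 6 of 11 and fell in 1 (adjusted p = 0.0706 and 0.0269). At 12 h 9 of 15 ribosome biogenesis genes fell (adjusted p = 0.00185), 7 of 12 sterol synthesis genes (0.0269), 4 of 7 heat shock genes (0.0269) and 5 of 27 ribosomal protein genes (0.0389), with 0 rising. Each adjusted over the list alone, 11 fell and 1 rose, 7 fell and 2 rose, 4 fell, and 6 fell. NPM1, a nucleolar chaperone, fell by 1.23 ± 0.15 and INSIG1, a brake on sterol synthesis, by 1.08 ± 0.09. The histone genes rose in 6 of 20 cases at each time with 0 falling, without a list call (adjusted p = 0.43 and 0.344). At 6 h they split 3 up and 2 down with arrays shifted to equal housekeeping medians, their median moving from 0.14 to -0.03.

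The limma fit called 2765 genes changed at 6 h in CCRF-CEM parent cells (1638 higher, 1127 lower, 425 by at least 2-fold) and 3744 at 12 h (2118 higher, 1626 lower, 625 by at least 2-fold). At 6 h 59.2% of the changed genes were higher, against 26.0% with arrays shifted to equal housekeeping medians.

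CCRF-CEM knockout cells raised VEGFA, the vascular growth factor, by 1.93 ± 0.41 log2 at 6 h and 2.65 ± 0.41 at 12 h (± SE, n = 3), and DNAJC28 by 1.65 ± 0.26 and 1.90 ± 0.26. VEGFA started from scattered knockout controls, with a mean of 4.31 and SD of 1.15, against 6.97 in parent controls. Its genotype difference did not pass at 6 h or 12 h (adjusted p = 0.556 and 0.145 by limma). DNAJC28 started from a knockout control mean of 3.25 (SD 0.57), near the lower quartile of the arrays, so the size of its rise is uncertain. RASL11B (1.60 ± 0.41), MSMB (1.57 ± 0.44) and RELB (1.47 ± 0.26) rose next at 6 h. At 12 h those were the kinase CDC42BPA (2.16 ± 0.46), the cadherin CDH24 (1.79 ± 0.23) and cortactin, CTTN (1.78 ± 0.40). CDC42BPA started from a mean of 2.75, below the lower quartile of every array, so the size of its rise is uncertain. LPP (-2.25 ± 0.18), HOXA6 (-2.17 ± 0.61) and IQUB (-2.06 ± 0.43) fell most at 6 h and IQUB (-2.74 ± 0.43), C7orf57 (-2.36 ± 0.20) and TENM1 (-2.33 ± 0.15) at 12 h. With the mean of all its probe sets in place of the brightest, IQUB stood at 0.123 at 6 h, in the other direction. Histone genes fell in 16 of 20 cases at each time with 0 rising (16 adjusted over the list alone). Their median log2 changes were -1.05 and -1.14, with adjusted p = 0.00027 and 0.000999 with an estimated correlation. H2BC3 fell by 1.62 ± 0.13 and 1.59 ± 0.13, and the linker histone gene H1-2 by 1.25 ± 0.13 and 1.22 ± 0.13.

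Immediate early genes in CCRF-CEM knockout cells rose in 5 and fell in 2 of 40 cases at 6 h (adjusted p = 0.427 with an estimated correlation) and rose in 1 and fell in 4 at 12 h (0.746). The counts adjusted over the list alone were 9 and 2, and 3 and 5, and KLF10 rose by 1.12 ± 0.13 at 6 h. NF-kB and cytokine genes rose in 1 and fell in 1 of 20 cases at 6 h and fell in 1 at 12 h (adjusted p = 0.178 and 0.781). Mitotic genes fell in 16 and 7 of 26 cases with 0 rising (adjusted p = 4e-05 and 0.036). DNA replication genes rose in 20 and 17 of 40 and fell in 1 and 0 (adjusted p = 0.000666 and 0.00333), and G1/S genes rose in 5 and 4 of 11 and fell in 0 and 1 (adjusted p = 0.00775 and 0.036). T-lineage markers fell in 4 and 6 of 20 cases with 0 rising (adjusted p = 0.00355 and 0.00333). Stress and unfolded protein response genes rose in 2 of 20 at 6 h and rose in 4 and fell in 1 at 12 h (0.23 and 0.036). Of 12 sterol synthesis genes 5 rose at 6 h (adjusted p = 0.00169), and of 20 chromatin remodeler genes 4 fell at 6 h (0.0287). Of 21 DNA damage checkpoint and recombination genes 7 rose at 12 h (0.036), the exonuclease EXO1 by 0.56 ± 0.09.

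The limma fit called 1434 genes changed at 6 h in CCRF-CEM knockout cells (784 higher, 650 lower, 192 by at least 2-fold) and 1828 at 12 h (1203 higher, 625 lower, 238 by at least 2-fold). The count at 6 h was 820, 931 and 809 without treated replicates 1, 2 and 3 and 827, 877 and 851 without control replicates 1, 2 and 3. The count at 12 h was 1064 without treated replicate 3 and 947 without control replicate 1. At 6 h 54.7% of the changed genes were higher, against 43.5% with arrays shifted to equal housekeeping medians and 40.6% after cyclic loess. Parent and knockout cells had 271 risen genes in common at 6 h (57.7 expected) and 346 fallen genes (32.9 expected), and 440 (114 expected) and 265 (45.6 expected) at 12 h. As in DU145, both lists rest on 1 estimate of spread per gene and are not independent.

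**Figure D2:**
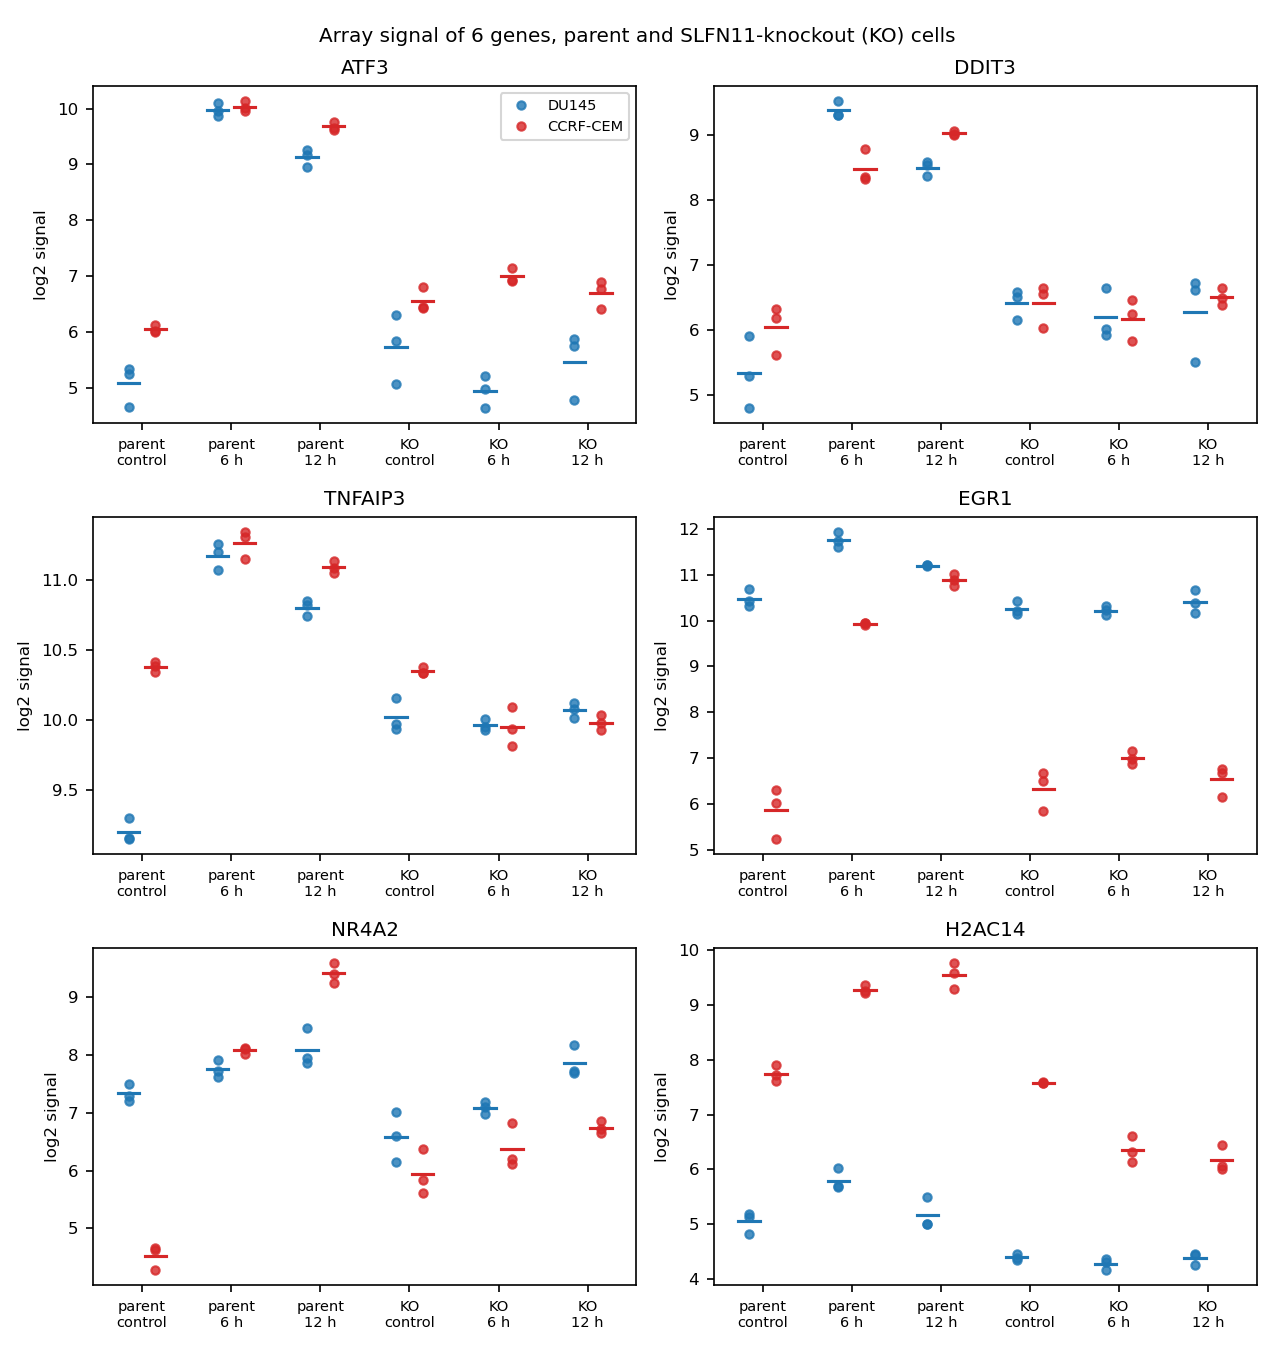
log2 signal of ATF3, DDIT3, TNFAIP3, EGR1, NR4A2 and the histone gene H2AC14 on each array, with 3 arrays (points) and their mean (bar) per group of line, genotype and treatment. ATF3 differed between the genotypes in its change by 5.69 log2 in DU145 and 3.54 in CCRF-CEM at 6 h.

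In CCRF-CEM the response differed most between parent and knockout cells for ATF3 (3.54 ± 0.19 at 6 h, adjusted p = 2.9e-07), EGR1 (3.41 ± 0.36) and the MAP kinase phosphatases DUSP10 (3.12 ± 0.23) and DUSP4 (3.12 ± 0.61), as log2 change in parent minus knockout cells ± SE. NR4A2 (3.11 ± 0.28) and the histone genes H2AC7 (3.03 ± 0.50) and H3C13 (2.89 ± 0.20) followed. DUSP4 had control means of 3.34 in parent and 3.42 in knockout cells, near the lower quartile of the arrays, so the size of its difference is uncertain. At 12 h it was largest for EGR1 (4.83 ± 0.36, adjusted p = 2.59e-06), NR4A2 (4.08 ± 0.28), RELB (3.89 ± 0.36), the costimulatory receptor TNFRSF9 (3.73 ± 1.05), H3C13 (3.53 ± 0.20) and ATF3 (3.50 ± 0.19). It was most negative for FMO2 (-2.33 ± 0.56), AGAP3 (-2.08 ± 0.41) and SERTAD4 (-1.92 ± 0.43) at 6 h. At 12 h this held for the transporter SLC22A10 (-2.92 ± 0.68), CDC42BPA (-2.62 ± 0.65) and the actin-bundling PLS3 (-2.49 ± 0.56).

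Immediate early genes differed between the CCRF-CEM genotypes as well. The genotype difference was larger (above 0) for 15 of 40 members at 6 h and smaller (below 0) for 0. Adjusted over the list alone these were 18 and 2 (median difference 0.56 log2, adjusted p = 0.00485 with an estimated correlation). At 12 h the genotype difference was larger for 21 and smaller for 1 (24 and 1, median 1.07, adjusted p = 0.00177). The 1 below 0 was MYC, at -0.76 ± 0.20, which fell more in parent than in knockout cells. JUN differed by 2.78 ± 0.20 and 3.07 ± 0.20, the nuclear receptor NR4A3 by 1.91 ± 0.26 and 2.27 ± 0.26 and the kinase SGK1 by 2.17 ± 0.48 and 1.98 ± 0.48. AP-1 genes were larger in 5 and 6 of 13 cases and smaller in 0 and 1 (6 and 0, and 7 and 2, adjusted over the list alone; adjusted p = 0.0044 and 0.00748). NF-kB and cytokine genes were larger in 7 and 8 of 20 cases and smaller in 0 (8 and 9; adjusted p = 0.00038 and 0.00103), with BIRC3 at 2.49 ± 0.32 and 1.93 ± 0.32. Histone genes had a difference above 0 in 15 and 16 of 20 cases and below 0 in 0 (16 above at each time adjusted over the list alone). Most of these genes fell in knockout cells, so the sign does not mean a larger change in parent cells. The median differences were 1.19 and 1.37 log2, with adjusted p = 0.00038 and 0.00103. H2AC14 differed by 2.77 ± 0.21 and 3.22 ± 0.21 and H3C4 by 2.02 ± 0.32 and 1.85 ± 0.32.

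Stress and unfolded protein response genes gave no list call in the CCRF-CEM genotype difference, with 5 larger and 1 smaller of 20 at 6 h and 5 larger and 4 smaller at 12 h (adjusted p = 0.115 and 0.444 with an estimated correlation). DDIT3 on its own differed by 2.67 ± 0.30 and 2.88 ± 0.30. T-lineage markers had a difference below 0 in 1 case at 6 h and 4 at 12 h and above 0 in 0 (adjusted p = 0.0323 and 0.0081). CD1A stood at -0.67 ± 0.13 and -1.46 ± 0.13. At 12 h mitotic genes had a difference above 0 in 1 and below 0 in 9 of 26 cases (adjusted p = 0.0081), with CCNB1 at -1.04 ± 0.16. Heat shock genes were smaller in 4 of 7 (0.0081), with HSPE1 at -0.86 ± 0.15, and ribosome biogenesis genes in 3 of 15 (0.00774), with NPM1 at -1.37 ± 0.21. DNA replication genes were smaller in 1 case at 6 h and larger in 2 and smaller in 6 at 12 h (0.386 and 0.415).

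In CCRF-CEM the genotype difference passed for 497 genes at 6 h, 342 higher and 155 lower, 192 by at least 2-fold, and for 1761 at 12 h, 808 higher and 953 lower, 525 by at least 2-fold. Of the 342 higher genes at 6 h 282 rose in parent cells and 72 fell in knockout cells, and of the 953 lower genes at 12 h 655 fell in parent cells. As in DU145, such overlap is partly built in. With arrays shifted to equal housekeeping medians the share of higher genes moved from 68.8% to 42.7% at 6 h and from 45.9% to 54.5% at 12 h. The count at 6 h was 323 and 318 without treated knockout replicates 1 and 2, and 324 without knockout control replicate 2. It was 316 and 319 without treated parent replicates 2 and 3, and 281 and 310 without parent control replicates 1 and 2.

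**Figure D3:**
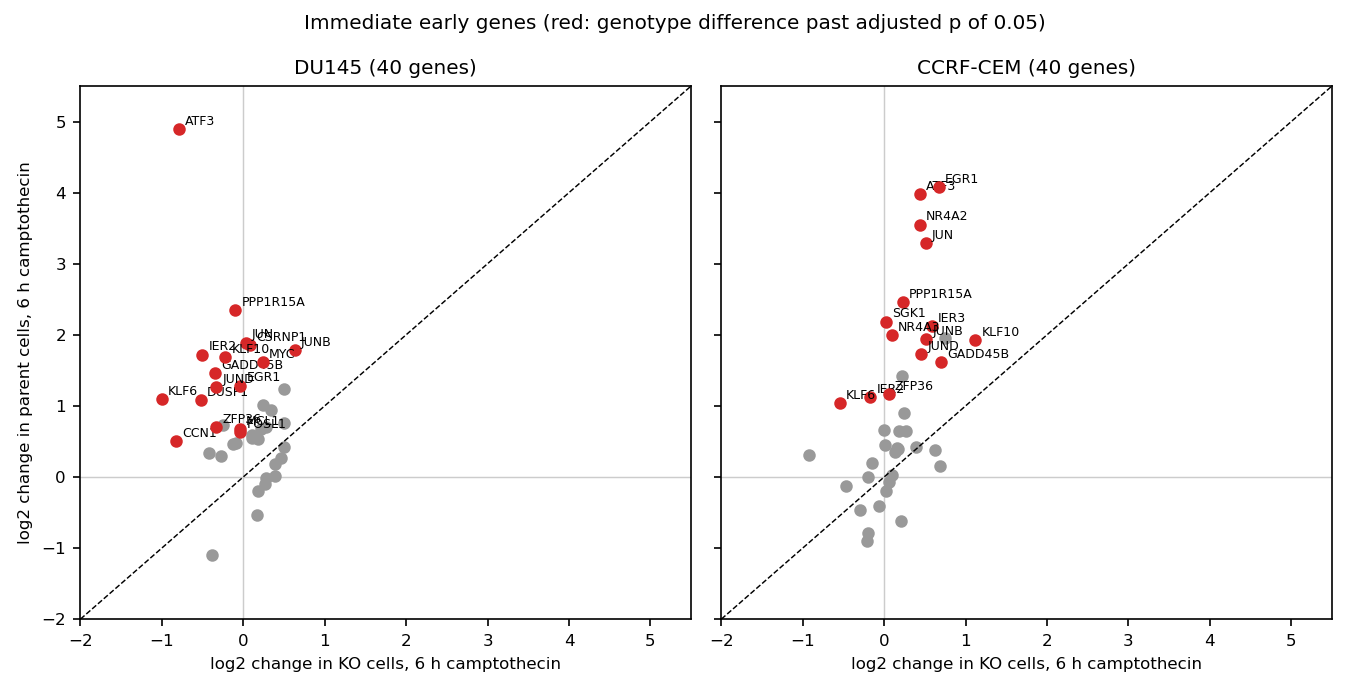
log2 change of each of the 40 immediate early genes after 6 h of camptothecin in knockout cells (x axis) and parent cells (y axis), 1 panel per line, with genes whose genotype difference passed in red. The red genes, 17 in DU145 and 15 in CCRF-CEM, lie above the diagonal.

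Both lines shared part of the genotype difference. At 6 h 57 genes were higher in both, against 2.67 expected for independent lists (Fisher's exact test, adjusted p = 3.92e-60). ATF3, DDIT3, EGR1, JUN, CXCL8 and TXNIP were among them, and 32 differed by at least 2-fold in each line. At 12 h 31 were higher in both, against 4.28 expected (adjusted p = 2.1e-18). This count was 18 and 17 without DU145 treated knockout replicates 1 and 2, 19 without treated parent replicate 2 and 20 without parent control replicate 2. The lower lists shared 8 genes at 12 h, against 5.69 expected (adjusted p = 0.283). Without 1 DU145 array that count was 2 for each treated knockout replicate, for knockout control replicate 2, for treated parent replicate 3 and for parent control replicate 3, 3 for treated parent replicate 2 and parent control replicate 1, and 1 for parent control replicate 2. At 6 h 3 lower genes were shared, SLC39A10, TMPO-AS1 and ZC3HAV1, named after their values were seen (0.515 expected, adjusted p = 0.0163). None was left without CCRF-CEM knockout control replicate 2, treated parent replicate 2 or parent control replicates 1 or 2. Their number was 1 without CCRF-CEM treated knockout replicates 1 or 2 or knockout control replicate 3, and without DU145 treated knockout replicates 1 or 3, knockout control replicate 2, treated parent replicates 2 or 3 or parent control replicates 2 or 3. Treated parent cells of both lines shared 500 higher genes at 6 h (92.9 expected) and 301 at 12 h. The lines share no arrays.

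Untreated knockout and parent cells also differed, more so in DU145. There SLC43A3, a purine base transporter, was higher in knockout cells by 4.82 ± 0.34 log2 (± SE, n = 3) and the chemokine CXCL5 by 4.13 ± 0.21. The interferon-induced membrane proteins IFITM3 and IFITM2 were higher by 3.90 ± 0.14 and 3.21 ± 0.12, the survival gene BCL2A1 by 3.40 ± 0.14 and HLA-DRA, a class II antigen-presenting chain, by 3.34 ± 0.26. The tight junction gene CLDN2 (-2.73 ± 0.38), DUSP4 (-2.68 ± 0.26), the natriuretic peptide receptor NPR1 (-2.49 ± 0.61) and TXNIP (-2.43 ± 0.20) were lower. Of 21 interferon-stimulated genes 10 were higher and 0 lower (10 adjusted over the list alone; adjusted p = 0.00668 with an estimated correlation), with IFIT3 at 1.90 ± 0.53 and IRF1 at 1.27 ± 0.19. Of 20 NF-kB and cytokine genes 6 were higher without a list call (9 adjusted over the list alone; adjusted p = 0.0713). Of 20 histone genes 2 were higher and 8 lower (adjusted p = 0.185), and of 40 DNA replication genes 1 higher and 9 lower (0.163). Of 26 mitotic genes 8 were higher (0.0936), and their median moved from 0.15 to -0.13 with arrays shifted to equal housekeeping medians. The limma fit called 2527 genes (1357 higher, 1170 lower, 537 by at least 2-fold), 53.7% of them higher against 11.6% with that shift. It called 1565 without knockout control replicate 1, 1453 without parent control replicate 2 and 1432 without parent control replicate 3.

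In untreated CCRF-CEM cells the guanine nucleotide exchange factor DOCK5 was higher in knockout cells by 2.97 ± 0.19 log2 (± SE, n = 3), RASSF8 by 2.66 ± 0.17 and the myosin gene MYO1D by 2.59 ± 0.55. CDC42BPA (-5.57 ± 0.46), the Golgi adaptor GGA2 (-4.02 ± 0.46), the histone gene H1-1 (-3.13 ± 0.17), VEGFA (-2.67 ± 0.41) and granzyme A, GZMA (-2.58 ± 0.27), were lower. The means of CDC42BPA and GGA2 in knockout cells were 2.75 and 3.26, near the lower quartile of the arrays (2.96 to 3.04), so background limits how large these differences can appear. The VEGFA value rests on knockout controls with an SD of 1.15. None of the 24 tested lists gave a call there with an estimated correlation, the lowest adjusted p being 0.0704 for T-lineage markers, of which 2 of 20 were higher (2 adjusted over the list alone). The limma fit called 337 genes (221 higher, 116 lower, 130 by at least 2-fold), 65.6% of them higher against 29.0% with arrays shifted to equal housekeeping medians. It called 208 without knockout control replicate 3, 212 without parent control replicate 1 and 223 without parent control replicate 3.

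The remaining lists gave few calls. Housekeeping genes rose in at most 2 and fell in at most 3 of 15 cases in any of the 14 comparisons, with no list call. Few calls do not mean that these genes stood still. Shifting arrays to equal medians of these 15 genes moved the median of all genes, as given below. Epithelial, B-lineage and myeloid, and fibroblast and endothelial markers gave no list call in either line, nor did T-lineage markers in DU145. BCL2 family and topoisomerase genes gave none either. PMAIP1, which encodes the BH3-only protein NOXA, rose in parent cells by 1.68 ± 0.11 in DU145 and 1.35 ± 0.08 in CCRF-CEM at 6 h. Schlafen family genes rose in DU145 in 3 of 6 cases at 12 h in parent and in knockout cells (adjusted p = 0.0352 and 0.0444), SLFN5 by 1.22 ± 0.15 and 1.06 ± 0.15. Interferon-stimulated genes gave no list call in the camptothecin comparisons or the genotype differences. Chromatin remodeler genes gave none in the genotype differences, with CHD2 larger in parent cells by 0.78 ± 0.15 in DU145 and 0.87 ± 0.19 in CCRF-CEM at 6 h.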

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

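Which genes to print here was chosen after the results were seen, while the test of whether the lines differ was fixed before the data were examined.

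The genotype difference was compared between DU145 and CCRF-CEM in a fit of all 36 arrays. MYC, the growth-promoting transcription factor and an immediate early gene, rose with camptothecin in DU145 parent cells and fell more in parent than in knockout cells of CCRF-CEM. At 12 h its genotype difference lay 1.71 log2 higher in DU145. HSPA5, the main chaperone of the endoplasmic reticulum, likewise lay 1.54 log2 higher in DU145 at 12 h. The separate fits gave genotype differences of 0.95 and -0.76 for MYC and 0.86 and -0.68 for HSPA5, the values for DU145 first.

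Over all genes 118 differed between the lines at 6 h, 47 larger in DU145 and 71 larger in CCRF-CEM, and 1064 at 12 h, 466 and 598. Leaving out DU145 treated parent replicate 3 gave 78 at 6 h. The 12 h set held 11 of the 20 histone genes and 9 of the 40 immediate early genes with a larger difference in CCRF-CEM, and 7 of 20 stress and unfolded protein response genes with a larger one in DU145. The lines differ in tissue of origin, growth and untreated genotype difference, and each has a single knockout group, so a difference between them may belong to the clone as well as to the cell type. No test here separates these.

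The 118 and 1064 genes were set against 99 other splits of the arrays between the lines, within genotype and treatment. The real grouping ranked 1 of 100 each time, the others giving at most 2 genes. This argues against a chance assignment of single arrays to the lines, at the lowest share that 100 splits can give. Splits that mix the real groups also widen the spread within groups, which lowers their counts. If the arrays of a group share a culture, a chance difference between cultures is not excluded.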

How the results depend on the processing

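The alternatives were fixed before the data were examined, apart from the overlap of the lines and the comparison of the lines with 1 array left out, which were added afterwards. Each group held 3 arrays, and the labels do not say that replicates are separate cultures, so the p-values measure only the spread between these samples, be it biological or technical. The direction of the immediate early gene lists held in both lines and at both times, and all 4 of their calls in the genotype difference held with the preset correlation. No call of any list was lost under that correlation, so this is a weak check. No called list changed direction under either rescaling of the arrays. The numbers of called genes moved more, and except where the construction of an alternative shows it the cause was not tested.

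With an adjusted p below 0.01, which by construction shortens every list, the genotype difference held 85 and 18 genes in DU145 at 6 h and 12 h and 145 and 658 in CCRF-CEM. Parent cells gave 1051 and 787 in DU145 and 1465 and 2243 in CCRF-CEM, knockout cells 794 and 990, and 516 and 674, and untreated knockout against parent cells 870 and 158. With only the arrays of the groups compared, which leaves fewer degrees of freedom, the genotype difference held 115 and 21 genes in DU145 and 179 in CCRF-CEM at 6 h. Parent cells then gave 866 and 387 in DU145 and 1284 and 2483 in CCRF-CEM, knockout cells 410 and 469, and 112 and 77, and untreated cells 511 and 56.

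With 1 fit of all 36 arrays the DU145 genotype difference rose to 506 and 629 genes, with a variance trend and robust moderation to 398 and 569, and in CCRF-CEM at 6 h the latter gave 849. Array weights gave 422 in DU145 at 6 h. With the level filter, which drops genes below the median level and so tests fewer, it was 517 and 683 in DU145, 1114 in CCRF-CEM at 6 h, and 2158 in CCRF-CEM knockout cells at 6 h. With replicate number as a block the DU145 genotype difference at 12 h fell to 126 genes. After removing group means, arrays with the same number correlated at -0.17 to 0.09 in DU145 and -0.05 to 0.16 in CCRF-CEM. The array most like a given one bore its own number for 3 of 18 arrays in DU145 and 12 of 18 in CCRF-CEM. The labels do not say what the numbers stand for, so a weak pairing in CCRF-CEM stays open, and the block is given only as an alternative.

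With each array shifted to equal housekeeping medians the genotype difference held 119 and 86 genes in DU145 and 1160 in CCRF-CEM at 12 h. Knockout cells gave 1216 in DU145 at 6 h and 886 and 1201 in CCRF-CEM, and untreated DU145 cells gave 4692. With that shift the median of all genes stood at -0.264 and -0.183 log2 in the untreated comparison of DU145 and CCRF-CEM. Without it these medians were 0.0088 and -0.016. In the genotype difference at 6 h it stood at -0.113 and -0.190, against -0.0048 and -0.040 without the shift. In CCRF-CEM parent cells at 6 h it stood at -0.187, against -0.016. Cyclic loess moved no such count by more than 1.5-fold.

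With the mean of all probe sets of a gene in place of the brightest, the genotype difference at 6 h held 500 genes in DU145 and 901 in CCRF-CEM. Parent cells gave 3437 and 2709 in DU145, knockout cells 3048 and 3489 in DU145 and 2232 in CCRF-CEM at 6 h, and untreated CCRF-CEM cells 771. Of 1507 results of listed or named genes 1202 were the same, 290 lost their call, 1 became a call and 14 had the opposite sign. With the housekeeping shift 342 of them lost their call, and with only the arrays of the groups compared 747 did. The results of opposite sign with the mean of all probe sets included, in CCRF-CEM parent cells at 12 h, HSP90AA1 at 0.0395. In the CCRF-CEM genotype difference at 12 h they were HSP90AA1 at 0.0363 and WDHD1 at 0.0311. In CCRF-CEM knockout cells at 6 h they were IQUB at 0.123, KRT8 at 0.00598 and PPIA at 0.0201. In DU145 they were CCND3 at -0.0213 in parent cells and NFKBIA at 0.315 and ZCWPW2 at -0.0628 in knockout cells at 6 h, CEBPB at -0.13 in the genotype difference at 12 h, and H2BC5 at 0.619, MCM7 at -0.395, SESN1 at -0.0199 and VWF at 0.0095 in untreated cells. With all probe sets tested, named or not, the genotype difference held 447 and 89 probe sets in DU145 and 818 and 4487 in CCRF-CEM, parent cells 12708 and 9080, and 14440 and 23653, knockout cells 9327 and 11577, and 6105 and 4466, and untreated cells 7704 and 1428.

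Leaving out 1 array at a time, the DU145 genotype difference held 144 to 228 genes at 6 h and 48 to 274 at 12 h, and that of CCRF-CEM 281 to 480 at 6 h and 1219 to 1568 at 12 h. DU145 parent cells gave 1398 to 1649 and 1133 to 1315, DU145 knockout cells 1168 to 1573 and 1375 to 1822, and CCRF-CEM knockout cells 809 to 931 and 947 to 1483. Untreated cells gave 1432 to 2258 in DU145 and 208 to 264 in CCRF-CEM. No called gene named or listed here changed sign in any of these fits, but over all of them 2184 gene results lost their call against 8699 that were the same.

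With genes changed by at least 2-fold in both lines, the lines shared 32 higher and 0 lower genes in the genotype difference at 6 h, 15 and 0 at 12 h, 62 higher and 23 lower in parent cells at 6 h, and 40 and 22 at 12 h. Leaving out 1 array gave 17 to 31 shared higher and 1 to 9 shared lower genes at 12 h, and 0 to 4 shared lower genes at 6 h. The difference between the lines held 289 genes at 6 h with the level filter and 78 to 141 without 1 array.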

Other observations

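The patterns and tests of this part were chosen after the results were seen, apart from the splits of the arrays and the test for exchanged treated arrays, which were written down before.

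At 12 h the chaperone gene HSPA5 had a genotype difference of 0.86 ± 0.15 log2 in DU145 and -0.68 ± 0.14 in CCRF-CEM, while DDIT3 had 3.30 ± 0.44 and 2.88 ± 0.30. T-lineage genes of CCRF-CEM fell with camptothecin in parent cells more than in knockout cells at 12 h, with RAG1 at -1.34 ± 0.19 and CD1B at -1.42 ± 0.18 in the genotype difference.

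In CCRF-CEM at both times and in DU145 at 6 h, replication-dependent histone genes fell in treated knockout cells and less or not in treated parent cells. In DU145 at 12 h they fell in both genotypes, and the genotype difference passed for 0 of 20. In CCRF-CEM at 12 h the median genotype difference was 1.37 log2, and the lower of its values under the housekeeping shift and cyclic loess was 1.399, above the bound of 0.5, so a shift between arrays left by the authors' normalization is excluded as the whole cause there. Members of 4 histone classes had a genotype difference that passed above 0 (H1 4 of 5, H2A 5 of 5, H2B 6 of 8, H3 1 of 1). Members of 3 classes were needed to exclude probe sets that share sequence between classes as the cause. Sharing within a class stays open. Fewer cells in S phase among treated knockout cells was tested through the DNA replication genes, whose median change in the 4 knockout comparisons was at its lowest 0.302. These genes are E2F targets induced before DNA synthesis begins, so a median above 0 excludes nothing and the explanation stays open. Histone transcripts are known to be degraded when DNA synthesis stops, so a stop of DNA synthesis in knockout cells is another hypothesis that these arrays could not test.

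Genes with many probe sets were over-represented among the fallen genes after camptothecin, an observation made while looking at gene structure and restated in probe sets per gene. Of the protein-coding genes, the 3581 with the most probe sets (20 or more) made up 45.5% of the fallen and 13.4% of the risen genes in DU145 parent cells at 6 h, 47.6% and 12.2% in DU145 knockout cells, 32.1% and 18.4% in CCRF-CEM parent cells and 40.6% and 13.8% in CCRF-CEM knockout cells. In CCRF-CEM parent cells at 12 h the shares were 25.1% and 22.8%, a difference that did not pass (Fisher's exact test over genes, p = 0.126). More of these genes rose than fell at 12 h in CCRF-CEM, 451 against 374 in parent cells and 227 against 185 in knockout cells. After cyclic loess the counts were 405 against 408 and 153 against 246, and with the mean of all probe sets 552 against 525 and 250 against 299. With arrays shifted to equal housekeeping medians they were 380 against 306 and 127 against 145, so which direction prevailed there depended on the processing. Within 5 bins of signal these genes had the lower median in 37 of 40 combinations, where 36 were needed, a bound set after the results were seen. The combinations share genes and control arrays, so they are not independent. This argues against signal level as the whole cause of the lower medians. It did not test the shares among the fallen and risen genes, and level within a bin stays open. The choice of the brightest of several probe sets is excluded as the whole cause. With the mean of all probe sets the smallest difference over 8 comparisons was 5.34 percentage points, with more among the fallen each time. A block of elongation by trapped topoisomerase I in genes with many exons, such as LPP (-2.29 ± 0.16 in DU145 knockout cells at 12 h), may be behind it, a hypothesis not tested here.

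The brightest SLFN11 probe set was not lower in the knockout cells, so exchanged labels were tested. Over the 537 genes in DU145 and 130 in CCRF-CEM that differed between the controls by at least 2-fold, 0 of 24 treated arrays lay nearer to the control arrays of the other genotype, which excludes treated parent and knockout arrays exchanged. The closest was DU145 parent 12 h replicate 3, at a median distance of 0.668 to its own controls and 0.679 to the others. Against the genotype labels exchanged for all DU145 arrays, 3 SLFN11 probe sets had all 9 knockout arrays below all 9 parent arrays and 0 above. Probe set 16843410 was higher in untreated knockout cells, though, at a mean of 8.85 against 8.14 in parent cells, and less so at 12 h, at 9.36 against 9.20. The position of the edit is not known, so this exchange stays open. For all CCRF-CEM arrays the test could not decide, since 1 probe set had all knockout arrays above and 0 below. Against an exchange, 16843409 was lower in untreated knockout cells of CCRF-CEM (-1.07 ± 0.14, adjusted p = 0.00233), and 57 genes were higher in the genotype difference of both lines at 6 h, against 2.67 expected. The first is 1 of 11 probe sets, and the second needs SLFN11 to act alike in both lines and the DU145 labels to be right, so the exchange stays open.

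Arrays were also split in other ways, to see how often a grouping by chance gives as many genes. For the genotype difference the real grouping ranked 1 of 100 splits in each case. In DU145 it gave 248 genes against at most 2 at 6 h and 251 against 2 at 12 h. In CCRF-CEM it gave 497 against 2 at 6 h and 1761 against 1 at 12 h. This argues against a chance assignment of single arrays to the groups, at the lowest share that 100 splits can give. Splits that mix the real groups also widen the spread within groups, which lowers their counts. If the arrays of a group share a culture, a chance difference between cultures is not excluded, since the splits exchange single arrays. For the comparisons of 3 against 3 arrays the real grouping also ranked 1, but 10 splits cannot give a share under 0.05. The real counts and the highest of the other splits were 2247 and 1 for DU145 parent cells at 6 h, 1711 and 1 at 12 h, 1940 and 1 for knockout cells at 6 h, 2232 and 0 at 12 h, and 2527 and 2 for untreated cells. In CCRF-CEM they were 2765 and 1, 3744 and 0, 1434 and 0, 1828 and 1, and 337 and 0.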
